A study of Homo sapiens with 18 samples.

How the data were processed

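The series holds 18 samples of UMRC2 cells, and the 6 RNA-seq libraries (2 each of shControl, shFTO#2 and shFTO#5, grouped by their sample titles) entered the analysis. The 12 m6A input and immunoprecipitation libraries were not analysed here. Total RNA was extracted with Qiagen columns from cells grown in serum-supplemented medium, per the labels' protocols. Trim Galore 0.4.2, STAR, RSEM and the hg38 build are named in the submitters' processing notes, without the role or order of each. The tool behind the differential test, the annotation release and the strand setting of the counting are not given in the sources used here. Nothing in the labels says that the 2 replicates of a group came from separate cultures, so the errors and p-values measure the spread between these libraries, which may be technical.

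The authors deposited FPKM values per library, as named in the file headers, for genes they had already called in the shFTO#5 comparison. The gene lengths used for FPKM stand beside them per the file headers. The deposited log2 fold changes, p-values and adjusted p-values are the authors' own, per the file headers, and the largest adjusted p was 0.0499, so the table holds genes at an adjusted p under 0.05. The number of genes tested, 9551 for shFTO#5 and 10038 for shFTO#2, was recovered from the ratio of adjusted p to p under the Benjamini-Hochberg method. The sign of the deposited log2 fold changes was control over knockdown, opposite to the wording of the header. With the sign reversed, direction matched the FPKM means in all 1242 genes, with a median difference of -0.03 in log2. All changes are given here as knockdown over control. The comparison columns were tied to a hairpin through the sample labels of the FPKM columns.

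In the shControl and shFTO#5 libraries, every FPKM value multiplied by gene length was a whole multiple of 1 step per library, which gives back whole reads and the total each library was scaled to. All 1242 values of these libraries were whole within 1e-05, as were the 561 assigned values of each shFTO#2 library with the length of the gene they were assigned to. These totals ranged from 14548533 to 18184675 reads, and the least covered listed gene had 81 reads. The replicates of each group differed by more than counting noise (chi-square per degree of freedom 3.58 for shControl, 4.54 for shFTO#2 and 2.41 for shFTO#5), so all were kept as separate libraries.

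The shFTO#2 values filled only 766 lines and did not belong to the genes on those lines. Each value was matched to listed genes whose length made it a whole read count in both libraries (tolerance 1e-05). The ratio of the knockdown values to the control of the listed gene also had to have the sign of the authors' fold change. Its log2 distance from that fold change had to be under 0.15, or under the size of the log2 fold change where that was larger. The longest chain of matches that kept the gene order was taken. It held 561 genes, against at most 50 in 100 shuffled orders. On a single simulated table of 750 entries, 600 of them from listed genes, the procedure without the level criterion placed 602 and put 600 in the right place. The library totals were given to that simulation. For the real shFTO#2 values they had to be inferred, a step that was not simulated. The 205 entries left over were used only in counts of the authors' calls.

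Limma 3.58.1 in R 4.3.3 was run with an intensity trend on log2(FPKM + 1) for genes with at least 1 FPKM in at least 2 libraries, which left all listed genes in. The shFTO#5 comparison used the shControl and shFTO#5 libraries on 1242 genes. The shFTO#2 comparison used all 3 groups on the 561 assigned genes, with one shared estimate of the spread. The design fixed before the data were examined had foreseen a table named for 1 knockdown and, for a table of called genes only, that no new calls against the control be made. The table turned out to be the shFTO#5 list, so its rules were applied to shFTO#5 as well. Because the fit saw only called genes, its estimate of the spread comes from genes chosen for a difference. On simulated data with 200 changed genes, limma recovered 100 of 100 at a log2 change of 1 and 100 of 100 at 2 in each comparison. It called 11 of 1041 genes simulated without a change for shFTO#5 and 6 of 360 for shFTO#2. The shFTO#2 simulation held only shControl and shFTO#2 libraries, so the fit of all 3 groups was not simulated. Log2 changes below 1 were not simulated, although the median absolute log2 change of the listed genes with shFTO#5 was 0.27. FTO was also tested with an exact permutation test.

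For 40 gene lists fixed before the data were examined, the members higher and lower by the authors' fold change were compared with all other listed genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists with at least 5 members. The test treats genes as independent, which they are not, and says nothing about enrichment, since only called genes were listed. For the same reason no count of called members adjusted over each gene list alone was made. Adjusted p-values from limma are over the 1242 or 561 genes in its fit. With random directions, 42 of 1250 simulated list tests (3.4%) had an unadjusted p under 0.05. Overlap between the hairpins was set beside 100 simulated draws of unchanged groups against the same controls. Gene positions are from GENCODE 29 on hg38, in which 1230 of 1242 identifiers (99.0%) were found. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

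Genes named in the text follow a rule fixed before the data were examined. It takes FTO first, then the 12 largest rises and 12 largest falls among the authors' calls whose groups did not overlap and whose higher group had at least 5 FPKM. It adds up to 4 called members with the smallest p from each list with at least 3, all called members of the m6A list, and SLC1A5, which was not analysed here. Some genes that the rule takes are not reported here. AKR1B1 and the gene families in the closing observations were chosen after their values were seen. Alternatives covered the pseudocount (0.1), the filter (none, or 5 FPKM), centring and quantile normalization, limma without trend, a replicate block, each library left out in turn, stricter thresholds and, added after the data were seen, other scalings and subsets for the gene lists and a match without the level criterion.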

Results

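RNA was sequenced from UMRC2, an established clear cell renal carcinoma line that lacks functional VHL, the protein that marks hypoxia-inducible factors for degradation. The cells carried a control short hairpin RNA (shControl) or 1 of 2 hairpins against FTO (shFTO#2 and shFTO#5). FTO is an RNA demethylase that removes N6-methyladenosine (m6A) from messenger RNA. Of the 18 samples in the series, 6 were RNA-seq libraries, 2 per group, and 12 were m6A input and immunoprecipitation libraries, which were not analysed here. The comparisons asked which transcripts differed from control cells when FTO was knocked down. The authors' deposited table held 1242 genes called in the shFTO#5 comparison, with FPKM (reads scaled to gene length and to the library total) in each library. The totals by which the FPKM values had been divided were 18184675 and 16247771 reads for shControl, 17448921 and 15585908 for shFTO#2, and 14548533 and 16806852 for shFTO#5. The listed genes held 32.1% and 32.4% of the shControl totals and 33.7% and 34.0% of the shFTO#5 totals. A listed gene had at least 81 reads in every library and a median of 1809.5 to 2544 reads per library.

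FTO itself, the gene that both hairpins target, was lower in all 4 knockdown libraries than in both control libraries. FTO (ENSG00000140718; hg38 chromosome 16, 53701692 to 54158512, plus strand, protein coding) measured 1.99 and 2.37 FPKM in the shControl libraries, from 426 and 454 reads. It measured 0.555 and 0.526 FPKM with shFTO#5, from 95 and 104 reads, and 0.882 and 0.720 FPKM with shFTO#2, from 181 and 132 reads. The group means were 2.18 ± 0.271 FPKM for shControl, 0.540 ± 0.0205 for shFTO#5 and 0.801 ± 0.114 for shFTO#2 (SD, n = 2 each), so that 24.8% and 36.7% of the control level were left. On the log2(FPKM + 1) scale, which understates the change of a gene at this level, FTO fell by 1.04 ± 0.07 (SE) with shFTO#5 and by 0.82 ± 0.07 with shFTO#2. In the authors' deposited table the log2 changes of FTO were -1.28 (adjusted p = 2.46e-21) and -0.90 (adjusted p = 7.69e-12). The exact two-sided permutation p was 0.333 for each hairpin, the smallest that 2 libraries against 2 allow. The difference between the hairpins in FTO did not pass limma's moderated test over the genes measured with both (log2 difference 0.22 ± 0.07, adjusted p = 0.0727).

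**Figure D1:**
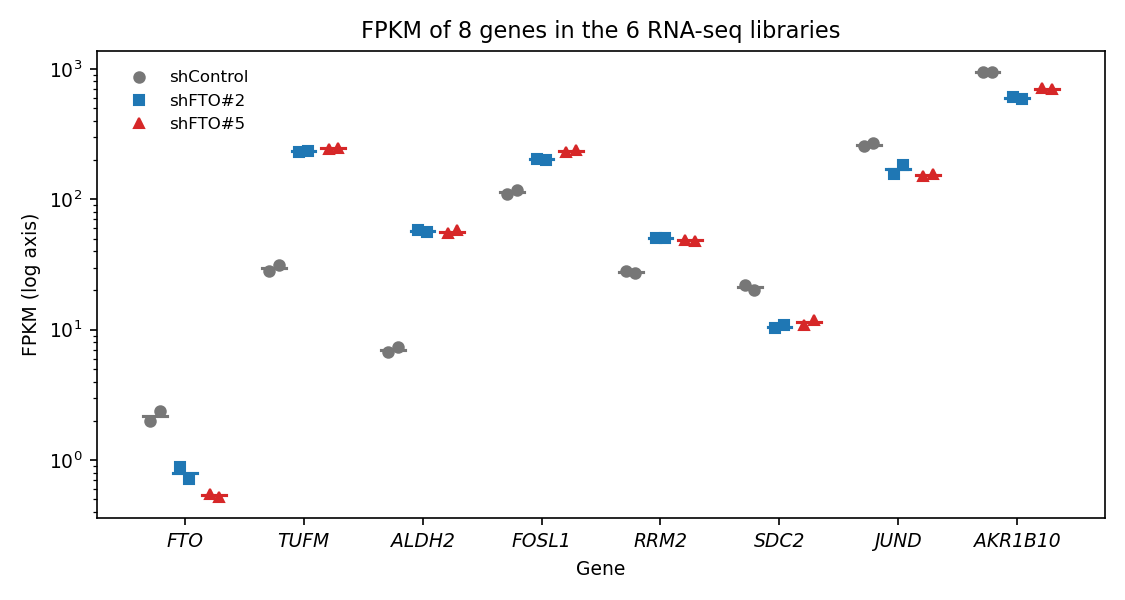
FPKM (log axis) of 8 genes in each of the 6 RNA-seq libraries: grey circles for shControl, blue squares for shFTO#2 and red triangles for shFTO#5, with a short line at each group mean (n = 2). FTO fell from 2.18 FPKM in shControl to 0.801 and 0.540 FPKM, while TUFM rose from 29.7 to 234 and 245 FPKM and ALDH2 from 7.04 to 57.3 and 56.5 FPKM.

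With shFTO#5, a pair of mitochondrial genes stood far above all other listed genes in the size of their rise. TUFM, the mitochondrial translation elongation factor, rose 8.24-fold from 29.7 ± 1.99 to 245 ± 4.56 FPKM, and ALDH2, the mitochondrial aldehyde dehydrogenase, rose 8.02-fold from 7.04 ± 0.397 to 56.5 ± 1.89 FPKM (SD, n = 2 per group). On the log2(FPKM + 1) scale, the next largest rise was that of FOSL1, an AP-1 transcription factor subunit, which went from 114 ± 5.85 to 236 ± 6.19 FPKM. On the same scale, the largest falls after FTO were in ACOT11, an acyl-CoA thioesterase, from 17.7 ± 0.249 to 8.61 ± 0.178 FPKM, and in SDC2, a cell surface heparan sulfate proteoglycan, from 21.1 ± 1.08 to 11.4 ± 0.654 FPKM. TUFM lies on chromosome 16 (28842411 to 28846408, minus strand) and ALDH2 on chromosome 12 (111766887 to 111817529, plus strand) of hg38, and both are protein coding.

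Other genes among the 12 largest rises included CDCP1, a transmembrane substrate of Src-family kinases (log2 change 0.97 ± 0.07, SE), TM4SF1, a small membrane protein (0.93 ± 0.05), EMP1, an epithelial membrane protein (0.92 ± 0.07), PVR, the poliovirus receptor (0.89 ± 0.04), and SLCO4A1, an organic anion transporter (0.88 ± 0.04). The integrin subunit ITGB3 rose by 0.80 ± 0.07, the long noncoding RNA CCAT1 by 0.94 ± 0.06, and RRM2, a subunit of ribonucleotide reductase, by 0.78 ± 0.04. Among the 12 largest falls were JUND, another AP-1 subunit (-0.78 ± 0.03), ERBB3, a receptor tyrosine kinase (-0.75 ± 0.06), and SLCO4C1, an organic anion transporter of the kidney (-0.75 ± 0.06). MSC, a basic helix-loop-helix repressor, fell by 0.72 ± 0.04, and GABARAPL1, a protein of autophagosome membranes, fell by 0.71 ± 0.06.

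In the authors' deposited table, 781 of the 1242 genes called with shFTO#5 were higher than in shControl and 461 were lower, so that 62.9% were higher. By the arithmetic of the p-values and adjusted p-values in the authors' deposited table, these calls were 13.0% of 9551 genes tested. Most changes were small: the median absolute log2 change was 0.27, and 11 genes changed at least 2-fold between FPKM means, 7 of them higher and 4 lower. In all 1242 genes the shFTO#5 libraries lay on one side of both shControl libraries, as the selection of called genes favours; chance gives 33.3% for 2 against 2 in genes that were not selected. The median SD between replicates was 0.03 in each group on the log2 scale. Because the table holds only genes that the authors' test had already called, limma's test of each hairpin against shControl on log2(FPKM + 1) served for ranks and errors and is not read as a new set of calls.

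Among the listed genes, 3 lists of ribosomal protein, ribosome biogenesis and mitosis genes held only genes that were higher with shFTO#5. All 22 listed cytosolic ribosomal protein genes were higher (median log2 change 0.15; adjusted p = 0.00066, Fisher's exact test), among them RPS18 (0.28 ± 0.03), RPS6 (0.23 ± 0.03) and RPS3 (0.19 ± 0.03). All 18 listed genes of MYC-driven ribosome biogenesis were higher (median 0.22; adjusted p = 0.00182, Fisher's exact test), including the nucleolar proteins NCL (0.19 ± 0.03) and NOLC1 (0.33 ± 0.04) and the pseudouridine synthase DKC1 (0.29 ± 0.04). All 21 listed G2/M and mitosis genes were higher (median 0.22; adjusted p = 0.000816, Fisher's exact test), including the anaphase activator CDC20 (0.24 ± 0.03), cyclin B1 (CCNB1, 0.36 ± 0.03), the mitotic kinase PLK1 (0.37 ± 0.04) and the spindle factor TPX2 (0.30 ± 0.03). The test compared higher against lower among a list's members and all other listed genes, two-sided, adjusted over the 25 lists with at least 5 members. After quantile normalization, 18 of the 22 ribosomal protein genes were higher, and that list no longer passed (adjusted p = 0.106). Ribosomal protein genes have many processed pseudogenes, and the treatment of reads shared with them is not given in the sources used here.

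All 15 listed members of the hypoxia-inducible factor pathway and its targets were also higher (median log2 change 0.19; adjusted p = 0.00867, Fisher's exact test). They included the growth factor TGFA (0.62 ± 0.05), cyclin D1 (CCND1, 0.44 ± 0.04) and, with a small change, the lactate dehydrogenase LDHA (0.11 ± 0.03). With each library centred on its median over the listed genes, 12 of the 15 were higher and the list did not pass (adjusted p = 0.254), whereas after quantile normalization 14 of the 15 were higher and it passed (adjusted p = 0.044). It did not pass without the members that another list holds (9 of 9 higher, adjusted p = 0.0808) or over the genes that also had shFTO#2 values (9 of 9 higher, adjusted p = 0.0779).

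Antioxidant genes controlled by the transcription factor NRF2 were lower with shFTO#5: 0 of 11 listed members were higher (median log2 change -0.28; adjusted p = 0.000427, Fisher's exact test). AKR1B10, an aldo-keto reductase, went from 943 ± 3.63 to 701 ± 9.25 FPKM (log2 change -0.43 ± 0.03). OSGIN1, an oxidative stress response gene, fell by 0.52 ± 0.04, UGDH, the UDP-glucose dehydrogenase, by 0.33 ± 0.03, and HMOX1, heme oxygenase, by 0.27 ± 0.03. The list passed under both other scalings, each again with 0 of 11 members higher. Centring lowered every change by 0.0887, so it could not make a member higher. Only quantile normalization could have done so.

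The other lists did not pass the adjusted test, and their counts are given for scale. Of 7 listed ATF4 and integrated stress response targets 1 was higher (adjusted p = 0.0511, Fisher's exact test), with log2 changes of -0.53 ± 0.03 for the stress regulator NUPR1, -0.29 ± 0.03 for PHGDH and -0.23 ± 0.03 for PSAT1, both enzymes of serine synthesis. Of 6 TGF-beta and SMAD targets 1 was higher (adjusted p = 0.0855), with -0.31 ± 0.03 for ID1 and -0.48 ± 0.03 for ID3, inhibitors of helix-loop-helix factors. All 9 DNA replication and G1/S genes (among them MCM7, a replicative helicase subunit, 0.26 ± 0.03) and all 8 housekeeping genes were higher (adjusted p = 0.0855 each), with 6 of the 8 housekeeping genes higher after centring. Of 12 heat shock proteins 11 were higher (adjusted p = 0.0885), such as HSPA8 (0.30 ± 0.03) and HSP90AB1 (0.27 ± 0.03), while the small heat shock protein CRYAB had -0.33 ± 0.03. That count was 9 after centring and 8 after quantile normalization. Of 13 integrin and focal adhesion genes 12 were higher (adjusted p = 0.0885), such as ITGA3 (0.60 ± 0.03) and the caveolar protein CAV1 (0.63 ± 0.03). All 5 matrix proteases and inhibitors were higher (adjusted p = 0.195), among them the urokinase PLAU (0.78 ± 0.06) and its receptor PLAUR (0.73 ± 0.07).

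All 7 NF-kB targets were higher (adjusted p = 0.106, Fisher's exact test), as were all 6 endoplasmic reticulum chaperones (0.141; 5 of 6 after quantile normalization) and all 5 apoptosis regulators (0.195). Of 5 amino acid transporters 1 was higher, with -0.31 ± 0.03 for the leucine transporter SLC7A5, and of 5 glutamine, glutamate and aspartate enzymes 1 was higher (adjusted p = 0.118 each). Of 13 growth factors and receptor tyrosine kinases 5 were higher (adjusted p = 0.14), and of 7 autophagy and lysosome genes 2 (0.16), with -0.49 ± 0.06 for the autophagy kinase ULK1. Of 6 renal tubule and nephron lineage genes 2 were higher (adjusted p = 0.23), with -0.58 ± 0.07 for the endocytic receptor LRP2 and -0.53 ± 0.06 for the kidney transcription factor PAX2. The YAP and TEAD targets and the Wnt and Notch genes each had 3 of 8 higher (adjusted p = 0.195). Of 11 glycolysis and pentose phosphate genes 9 were higher (adjusted p = 0.248), and 4 after centring. Immediate early genes and fatty acid and lipid droplet genes each had 6 of 9 higher (adjusted p = 1.0). Besides FTO, the called members of the m6A list were YTHDF3, an m6A reader (0.15 ± 0.05), and HNRNPA2B1, an RNA-binding protein (0.08 ± 0.03), which had -0.01 ± 0.03 after centring.

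Lists for immune and endothelial cells, mitochondrially encoded transcripts, replication-dependent histones, interferon-stimulated genes and antigen presentation had 0 members among the 1242 genes analysed here. The fibroblast and pericyte list had 1 member, which was lower. The remaining lists had too few members for a test: 2 of 3 higher for p53 targets, for cholesterol synthesis (1 of 3 after centring) and for the tricarboxylic acid cycle, 3 of 4 for epithelial and mesenchymal state genes, 1 of 2 for collagens, 2 of 2 for oxidative phosphorylation (1 of 2 after centring) and 1 of 1 for renal tumour suppressors.

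**Figure D2:**
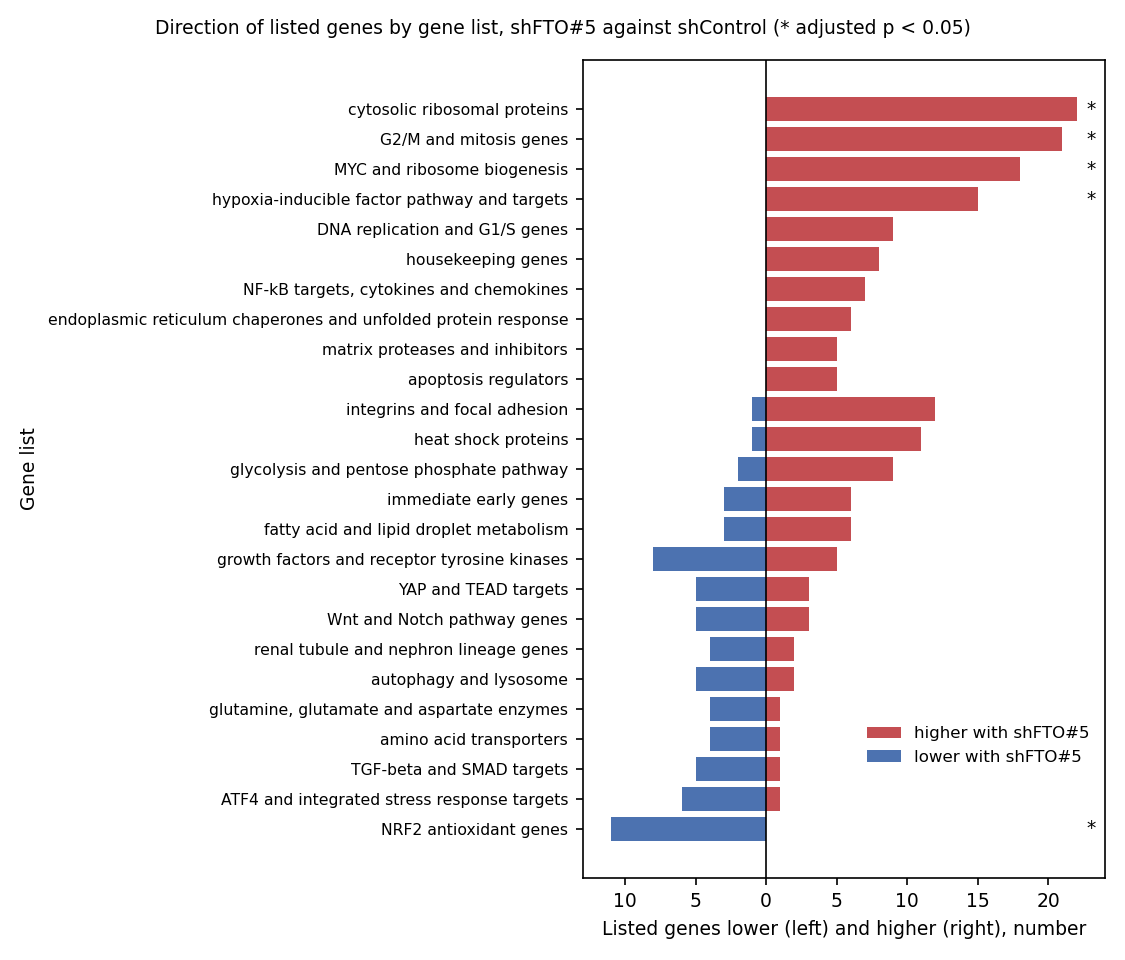
Number of listed genes higher (red, right) and lower (blue, left) with shFTO#5 than in shControl for the 25 gene lists with at least 5 members, with an asterisk where the adjusted p of Fisher's exact test was below 0.05. All 22 ribosomal protein, 21 mitosis, 18 ribosome biogenesis and 15 hypoxia-inducible factor genes were higher and all 11 NRF2 genes lower; with each library centred, 20 of the ribosomal protein and 12 of the hypoxia-inducible factor genes were higher.

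With shFTO#2, TUFM and ALDH2 again had the largest rise among the 561 assigned genes, at 234 ± 2.49 and 57.3 ± 1.58 FPKM (SD, n = 2). These values are 7.86 and 8.14 times the control level. SLCO4A1 (log2 change 0.97 ± 0.04, SE), the urokinase gene PLAU (0.93 ± 0.06), CCAT1 (0.85 ± 0.07), PVR (0.84 ± 0.03), RRM2 (0.84 ± 0.04) and CDCP1 (0.83 ± 0.06) rose, as did HMGA2, a chromatin architectural protein (0.84 ± 0.06), and FOSL1 (0.82 ± 0.04). Among the assigned genes, SDC2 (-0.94 ± 0.06), MSC (-0.93 ± 0.05) and MARCKS, an actin-binding substrate of protein kinase C (-0.86 ± 0.06), had the largest falls on the log2(FPKM + 1) scale, which understates that of FTO. Calls left without a gene name were not ranked. By FPKM means, 4 of the assigned genes were at least 2-fold higher and 4 at least 2-fold lower. NR0B1, an orphan nuclear receptor (-0.83 ± 0.04), ACOT11 (-0.81 ± 0.06), CYP4F11, a fatty acid hydroxylase (-0.74 ± 0.04), and GABARAPL1 (-0.74 ± 0.07) also fell.

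These values rest on a reassignment of part of the table. The shFTO#2 values filled 766 lines in a gene order of their own, and only 4 and 6 of them were whole read counts with the length of the gene on their own line in the first and second library. Through whole reads, gene order and control level, 561 of the 766 calls (73.2%) were assigned to a listed gene, and the remaining 205 calls, 66 higher and 139 lower, stayed without a name. In the authors' deposited table, 419 of the 766 shFTO#2 calls were higher than in shControl and 347 lower (54.7% higher), 7.6% of the 10038 genes tested. Of the 561 assigned genes, 353 were higher and 208 lower, and all of them were also calls of shFTO#5, since only those were listed by name. Centring each library on its median over these genes shifted the log2 changes by -0.15. Of 399 genes then past limma's threshold, 191 were higher and 208 lower (47.9% higher), against 62.9% higher without centring.

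Among the assigned genes, NRF2 antioxidant genes were lower with shFTO#2 as well: 0 of 10 were higher (median log2 change -0.43; adjusted p = 0.000555, Fisher's exact test over 13 lists with at least 5 members). All assigned genes had also been called with shFTO#5 against the same controls, and 559 of the 561 had the same direction. The shFTO#2 tests are therefore no independent check of the shFTO#5 ones. AKR1B10 went to 598 ± 13.5 FPKM (-0.66 ± 0.03), OSGIN1 fell by 0.62 ± 0.04 and HMOX1 by 0.51 ± 0.03. Relative to the centred libraries the NRF2 list still passed with 0 of 10 higher (adjusted p = 0.00393, Fisher's exact test). Centring lowered every shFTO#2 change, so that count could not rise. After quantile normalization the NRF2 list passed with 1 of 10 higher (adjusted p = 0.0144). All 11 integrin and focal adhesion genes (median 0.30; adjusted p = 0.0379), with ITGA3 at 0.71 ± 0.04 and CAV1 at 0.46 ± 0.03, and all 11 ribosomal protein genes (median 0.15; adjusted p = 0.0379), with RPS18 at 0.22 ± 0.03, were higher as deposited. Neither list passed under the other scalings: integrins had 10 of 11 higher after centring (adjusted p = 0.153) and 11 of 11 after quantile normalization (0.0554). Ribosomal protein genes had 5 of 11 higher after centring (adjusted p = 0.72) and 10 of 11 after quantile normalization (0.151).

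The hypoxia-inducible factor list (9 of 9 higher) and the G2/M list (8 of 8) did not pass with shFTO#2 (adjusted p = 0.0782 each, Fisher's exact test), and each had 6 members higher with centring and 8 with quantile normalization. Of the other tested lists, all 6 endoplasmic reticulum chaperones (adjusted p = 0.194), all 5 matrix proteases (0.265), 6 of 7 heat shock proteins (0.348), 5 of 6 glycolysis genes (0.497), 2 of 7 YAP and TEAD targets (0.2), 2 of 6 Wnt and Notch genes (0.291), 4 of 8 growth factors and receptor kinases (0.517) and 3 of 5 immediate early genes (1.0) were higher. With centring, the heat shock proteins had 4 of 7 and the glycolysis genes 2 of 6 higher. A further 18 lists had 1 to 4 members and 9 had 0 members among the assigned genes.

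The hairpins moved the same named genes in the same direction for nearly all genes that could be compared. Of the 561 genes called with both, 353 were higher with both, 206 were lower with both and 2 differed in direction. Those 2, named here after their values were seen, were CSF1, a macrophage growth factor (0.19 ± 0.05 with shFTO#5 and -0.24 ± 0.05 with shFTO#2), and AKR1B1, an aldose reductase (0.07 ± 0.03 and -0.18 ± 0.02). After centring, AKR1B1 with shFTO#5 was -0.02 ± 0.03, so that its direction was not settled. Independent lists of these sizes would share 99.6 genes, 34.3 of them higher and 16.7 lower, taking the 9551 genes of the shFTO#5 test as those tested in both.

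The log2 changes of the 2 hairpins had a Pearson correlation of 0.97 across the 561 genes, which are not independent replicates. Both comparisons used the same control libraries, and the genes were chosen for being called with both. In 100 simulated draws of groups without any change against shared controls, the correlation averaged 0.494 (highest 0.595) and the share of genes with the same sign 66.8% (highest 70.4%), against 99.6% observed. Among simulated genes with an unadjusted p under 0.05 against both groups, a mean of 9.09 per draw, the share with the same sign was 96.0%. The covariance was 0.168 observed and 0.00129 in the simulation. With 1 control library per hairpin, a split chosen after the results were seen, the correlation was 0.957 one way and 0.955 the other, with a covariance of 0.167 and 559 of the 561 genes of the same sign each way. The genes were still those called against both control libraries. The simulated groups shared their controls too, but the simulated correlation, covariance and 66.8% share are over all simulated genes. Part of the excess over these values may therefore come from the choice of called genes. Only the 96.0% is over simulated genes chosen for passing against both groups, at an unadjusted p. Per gene, the shFTO#2 change was a median of 0.946 times the shFTO#5 change, and 315 of the 561 genes changed less with shFTO#2.

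**Figure D3:**
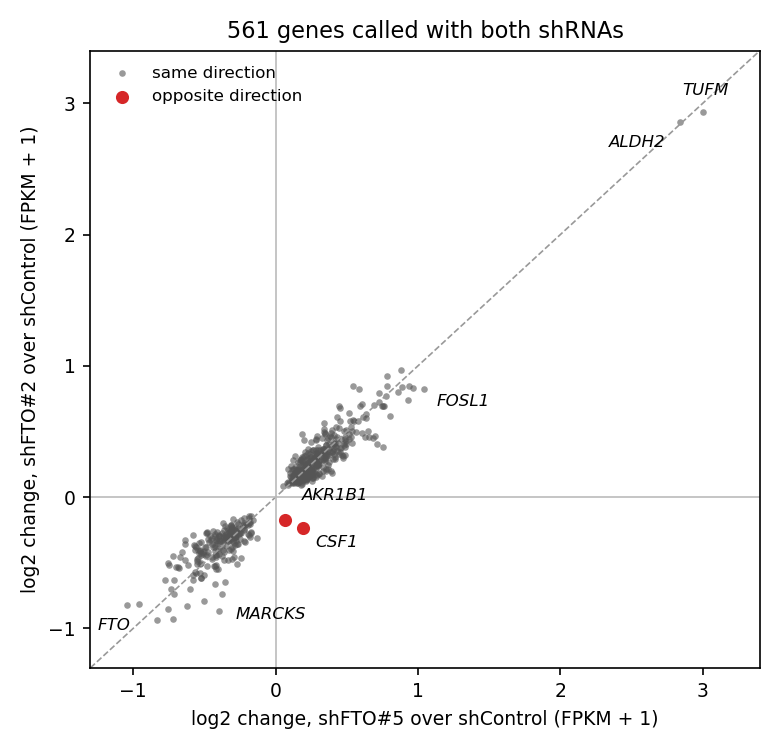
Log2 change over shControl (FPKM + 1) with shFTO#5 (x axis) and shFTO#2 (y axis) for the 561 genes called with both, where each point is a gene and the dashed line marks equal change. TUFM and ALDH2 lie near 3 on both axes, 559 genes lie in the quadrants of equal direction, and the 2 red points, AKR1B1 and CSF1, have opposite directions.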

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

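All tests in this part were chosen only after the results were seen. Genes that responded more to one hairpin than to the other were found by limma's test of the difference between shFTO#2 and shFTO#5 over the 561 assigned genes in the 3-group fit, in which the control libraries enter through the shared estimate of the spread. At an adjusted p under 0.05, 77 genes differed (166 at an unadjusted p under 0.05), 34 with higher values in shFTO#2 and 43 with higher values in shFTO#5, by a median of 0.18 in log2. The change against the control was larger with shFTO#5 for 46 of them and larger with shFTO#2 for 31. The count rests on single libraries: without shFTO#5 replicate 1, limma called 0 genes (113 at an unadjusted p), without shFTO#5 replicate 2 it called 6, and after quantile normalization 42. The balance of directions depends on the settings too: after centring, 24 genes were higher in shFTO#2 and 87 in shFTO#5, and without shFTO#2 replicate 1 the counts were 42 and 29.

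Of the named genes, 22 were among the 77, given here as shFTO#2 minus shFTO#5 in log2. AKR1B10 (-0.23), HMOX1 (-0.23), CYP4F11 (-0.36) and AKR1B1 (-0.25) were lower with shFTO#2, while OSGIN1 (-0.10, limma's adjusted p = 0.149) and UGDH (-0.08, adjusted p = 0.177) did not pass. MARCKS (-0.47), the nuclear receptor NR0B1 (-0.21) and the repressor MSC (-0.20) were also lower with shFTO#2. Genes that rose with shFTO#5 and stood lower with shFTO#2 were FOSL1 (-0.22), TM4SF1 (-0.18) and CAV1 (-0.17), the cell cycle genes CCNB1 (-0.14), PLK1 (-0.15) and MCM7 (-0.12), the nucleolar gene NOLC1 (-0.13) and the chaperone HSP90AB1 (-0.11). CSF1 (-0.43) was lower with shFTO#2, with opposite directions against the control. Higher with shFTO#2 were HMGA2 (0.30), which rose with both hairpins, and ERBB3 (0.25), SLCO4C1 (0.23), LRP2 (0.29), ULK1 (0.22) and ID1 (0.0921), whose values were below the control with both. No explanation of these differences was tested.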

How the results depend on the processing

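The other scalings, subsets and match for the gene lists, the settings applied to the authors' shFTO#5 calls and the 3-group fit were chosen only after the results were seen. Of 655 values of named genes under alternatives, 640 kept their direction and their side of the threshold. With the replicate number as a block, limma passed 1242 shFTO#5 genes and 561 shFTO#2 genes (1238 and 561 without it), and 105 genes differed between hairpins (77 without it). The lists (5 and 3), FTO (-1.04 and -0.82) and the 559 shared calls could not change with the block, since no groups overlapped and a mean of pair differences equals the difference of means. The deviations of same-numbered libraries correlated at 0.0884 for shControl with shFTO#5 and 0.218 for shControl with shFTO#2, but with 2 pairs the numbers were not taken as a pairing. Leaving out each library in turn, with the lone sample assumed to vary like the other groups, gave 1182 to 1211 genes for shFTO#5, 555 to 560 for shFTO#2, FTO changes of -1.13 to -0.96 and of -0.91 to -0.73. The lists (5 to 5 and 3 to 3) and the directions of the authors' 1242 and 561 genes could not change, because no groups overlapped.

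A stricter adjusted p under 0.01 left 818 of the authors' shFTO#5 calls (529 higher, 289 lower), 494 of the shFTO#2 calls (287 and 207) and 365 shared calls (241 and 124). A minimum of 2-fold left 4 shFTO#5 and 2 shFTO#2 calls, by the authors' fold changes and by limma alike, and FPKM means gave 11 for shFTO#5 and 4 higher and 4 lower assigned genes for shFTO#2. For FTO, the authors' fold changes and limma both gave smaller changes than FPKM means. With shFTO#2, FTO was at 36.7% of the control mean. Its log2 change was -0.90 by the authors and -0.82 by limma, so it dropped out. Fitting the 3 groups together limited shFTO#5 to assigned genes, of which 560 passed. With a pseudocount of 0.1 the FTO change was -1.83 for shFTO#5 and -1.34 for shFTO#2, since FTO lies near the pseudocount of the values given in the report. Past limma's threshold for shFTO#5 were 995 genes after centring (534 higher, 461 lower) and 1005 after quantile normalization. Over assigned genes alone, 3 lists passed for shFTO#5, with fewer members per list. With centring 1 list (NRF2) passed for shFTO#2, and 1 (NRF2) with quantile normalization; the ribosomal protein list turned direction after centring (adjusted p = 0.72, 5 of 11 higher). The median change of its members as deposited, 0.15, was no larger than the shift of -0.15 that centring made. With shFTO#5, HNRNPA2B1 turned to -0.0128 after centring and -0.0073 after quantile normalization, and AKR1B1 to -0.0192 after centring, which shifted all changes by -0.0887, more than either gene had changed. The cause of the changes under quantile normalization was not tested. The centring set holds only called genes, mostly higher ones, so it cannot be read as neutral. The analyses for count tables (DESeq2, count filters) and the camera test were not run, since no count table or background of other genes was used here, and no list kept 5 members at 2-fold. Every gene with values here had at least 81 reads in each library; what depth limits for genes outside the table was not analysed here.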

Other observations

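The tests of TUFM and ALDH2 against the control level and the FTO level, of the order of the shFTO#2 values, of a scaling offset and of gene properties with the lists picked each time were chosen only after the results were seen, as were the gene families. Families looked up by gene symbol, of which some members are also in the fixed lists, are given as counts without a test. All 12 listed genes with an EIF symbol were higher with shFTO#5 (log2 changes 0.07 to 0.33), and 10 after quantile normalization. They include EIF4EBP1, a binding protein of an initiation factor, so the count is not of initiation factors alone. Also higher with shFTO#5 were all 7 listed subunits of the CCT chaperonin (0.13 to 0.31) and all 6 MCM helicase subunits (0.18 to 0.26). All 10 listed proteasome genes were higher (0.09 to 0.29), and 9 after quantile normalization. All 8 HNRNP genes were higher by 0.08 to 0.13, with 7 higher after centring and 6 after quantile normalization. With shFTO#2, all 4 assigned CCT genes (3 after centring) and all 3 assigned MCM genes (1 after centring) were higher.

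All 6 listed S100 calcium-binding proteins were higher with shFTO#5 (0.14 to 0.49; 5 after quantile normalization) and all 6 with shFTO#2 under each scaling. The 5 listed TNF receptor superfamily genes were higher with shFTO#5 (0.11 to 0.52) under each scaling. The 4 ID genes, inhibitors of helix-loop-helix transcription factors, were lower with shFTO#5 (-0.48 to -0.31), and the 3 assigned with shFTO#2 were lower too, each time under each scaling. Centring, which lowered every change, could not raise them. Among 5 listed FGF receptor family genes, FGFR1 was the 1 higher with shFTO#5 and 4 were lower. Of 7 listed aldehyde dehydrogenase genes (median -0.45 over all 7), ALDH2 alone was higher and 6 were lower, under each scaling. For the 6 lower genes centring could not change the direction.

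The rise of TUFM and ALDH2 to about 8 times the control was far outside the range of all other listed genes, and both hairpins gave nearly the same level. The difference between the knockdown groups was at most 0.0233 of the change against the control. This is what a change confined to the control libraries would give, and such a change may account for the pattern. TUFM and ALDH2 could, for example, have been lowered by the control hairpin or have differed in the control cells. In the shFTO#2 to shFTO#5 ratio of log2 changes they stood at percentiles 52.9 and 57.9 of the 561 genes. Near-equal changes were thus not particular to them, and a change confined to the control libraries was not tested for the other genes. A response to FTO loss that is already complete at the FTO level left with shFTO#2 stays open as well. The shFTO#2 to shFTO#5 ratio of log2 changes was 0.977 for TUFM and 1.01 for ALDH2, between the median (0.946) and the third quartile (1.15) of the 561 genes. The FTO difference between the hairpins did not pass limma's test, so these ratios cannot tell a graded response from a complete one. A shared seed site of the control hairpin cannot be told apart from these explanations, since its sequence was not used here and none of the 235 words of 7 bases in both 3' untranslated regions passed (smallest Bonferroni-adjusted p = 1.0, smallest unadjusted p = 0.01).

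The joint rise of listed ribosomal protein, ribosome biogenesis and mitosis genes with shFTO#5 was set against length, GC content and control FPKM, with other listed genes matched on these. None of 10000 matched sets for the 61 members were all higher (0.0% of sets, median 80.3% higher, highest 93.4%). Lists picked for being all higher tend to exceed matched sets, so this does not settle whether these properties were the whole cause. The matched sets were higher more often than the genes outside each list (62.2% to 62.3%). These properties thus went with part of the excess. How close the matches were was not measured. Because the lists had been picked for being all higher, all 25 tested lists were also replaced and the 3 largest all-higher sets picked each time. None of 10000 draws held 61 genes (0.0%, median 17, highest 49). The 3 lists were the largest of the 25, so only draws with all 3 of their replacements all higher could hold 61 genes. The second test therefore adds little to the first. All members of the biogenesis and mitosis lists stayed higher after centring and after quantile normalization (adjusted p of 0.000482 to 0.00117, Fisher's exact test). After centring this followed from the uncentred changes, since the lowest in each list (0.1152 and 0.1127) exceeded the shift of 0.0887. The members' changes were thus larger than that shift. Whether an offset was the cause stays undecided, because only genes with changes large enough to be called were listed. All 8 listed housekeeping genes were also higher, 6 after centring and 8 after quantile normalization. A larger offset was not tested. After the 2 scalings the lowest biogenesis or mitosis member stood at 0.024 ± 0.0512 and 0.0272 ± 0.025 (SE), so not every member was higher beyond its error. With shFTO#2, 6 of 8 mitosis genes were higher after centring and 8 after quantile normalization. For the ribosomal proteins an offset cannot be told apart from a response, since 20 of 22 were higher after centring (adjusted p = 0.02) and 18 of 22 after quantile normalization (adjusted p = 0.106, Fisher's exact test), and both scalings rest on called genes alone. A response of the biogenesis and mitosis genes to FTO knockdown stays open as a hypothesis, found and tested on the same data.

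The shFTO#2 values out of step with their gene names may come from a block pasted in its own gene order. Matched on whole reads alone, 562 values followed each other in the order of the listed genes, against at most 63 in 100 shuffled orders. If the values are read line by line as they stand, they are assigned to the wrong genes for nearly all lines, so a reuse of that part of the table needs the reassignment or the original. No biological explanation was tested.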
